A study of Mus musculus with 20 samples.

How the data were processed

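The samples are CUT&RUN libraries of mouse bone-marrow-derived macrophages, WT or KO, untreated or given 100 ng/mL LPS for 30 min or 8 h. Antibodies against p65 and SOCS1 gave the 12 libraries analysed, 1 for each antibody, genotype and treatment. The labels list 20 samples; 6 IgG libraries entered through the authors' peak calls alone, and 2 internal control libraries were not used here. The design text names the KO as NOS1, while the title is about SOCS1, and the peak lists do not settle which gene was disrupted. KO peaks inside Nos1 show only that those stretches of the gene are present in KO cells.

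Per the labels, the authors trimmed reads with cutadapt, aligned them to mm10 with Bowtie2 2.4.1 and called peaks with HOMER 4.11. Per the file headers, each peak list was called by findPeaks in its factor mode from 1 library against the IgG library of the same genotype and treatment. The call used an FDR of 0.001, at least 4-fold enrichment over IgG and over the surrounding 10 kb with a Poisson p of at most 0.0001, a clonal limit of 2 and at most 1 tag per bp. Peak size and fragment length were estimated for each library, so peaks are 222 to 493 bp wide. In the deposited lists the signal is the tag count of the peak scaled by the authors to a library of 10000000 tags. The score is the authors' findPeaks score, tags in the peak under the limit of 1 tag per bp, not scaled to depth. The expected count is, per the file headers, the number of IgG tags in the peak, with a floor of 0.5. The ratio is the authors' fold of the peak over IgG, over the local background or over the clonal expectation. The p-value of each peak is the authors' Poisson p, not adjusted, and the fraction is the authors' focus ratio, the share of tags on the expected side of the peak centre. None of these authors' statistics was recomputed; scores and folds served to describe, rank and filter peaks within a list, and a score in the text belongs to its own list. The labels mention an E. coli spike-in, which was not used here.

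Depth was 7.69, 13.3 and 10.6 M tags (10 M are 10000000) for p65 in WT cells (control, 30 min, 8 h) and 8.79, 18.4 and 11.0 M in KO cells. For SOCS1 it was 6.93, 9.74 and 9.51 M in WT cells and 8.06, 9.11 and 7.77 M in KO cells. The IgG libraries held 6.85 to 9.43 M tags, worked out from the authors' scaling. The lowest score in a list was 7 to 12 tags, so a site with fewer tags could not be called, and a site absent from a list is not shown to be unbound. With 1 library per group, variation between animals or experiments cannot be estimated. Exact 95% intervals for shares cover counting error only, and no test between groups was made.

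Peaks of 2 lists were counted as shared where they overlapped by at least 1 bp. For each share, the share expected if the lists were independent within the 96700 merged regions of all 12 lists was computed, and so was the mean of 100 random placements of the peaks on the genome, which lay between 0.22% and 1.25% for all pairs of lists. Lists of the same genotype and treatment share an IgG library. The comparisons were LPS against control for each antibody and genotype, KO against WT for each antibody and treatment, and p65 against SOCS1 within each genotype and treatment. Shares of p65 peaks with SOCS1 were also counted in 4 equal groups by p65 score, and by whether the p65 site was called at 30 min, at 8 h or at both. For these time classes a p65 site counted as called at both times where centres lay within 500 bp, while overlap with SOCS1 kept the 1 bp rule. Centres within 500 bp also served to find WT 8 h sites of low and high local fold in other lists.

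The gene table used is of the mm10 build, and its 21887 protein-coding genes with a unique symbol on chromosomes 1 to 19, X and Y were kept. In all that follows, "genes" and "all genes" mean these, and non-coding genes were left out. The table has no strand, so the plan to link peaks to transcription start sites was changed: a peak was linked to every gene with either end within 10 kb of the peak centre. Exons, introns and start sites could not be told apart, and peaks were placed within 1 kb of a gene end, elsewhere inside a gene or elsewhere outside genes. No genome sequence was at hand, so the planned count of sequence motifs was not run.

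For gene groups, 20 lists were fixed before the data were seen: NF-κB subunits and feedback inhibitors, pro-inflammatory cytokines, chemokines, interferon-stimulated genes, JAK-STAT components and the SOCS family, TLR4 signalling, immediate-early genes, anti-inflammatory and tolerance genes, alternative activation genes, antimicrobial and redox genes, glycolysis and HIF-1 genes, macrophage identity genes, antigen presentation, cell death, cholesterol and lipid genes, housekeeping genes, markers of neutrophils, lymphocytes and dendritic cells, and neuronal and hepatic genes. Of 375 members, 372 were found among the protein-coding genes kept, and Cxcl11, Mx1 and Mx2 were not. The number of members with a peak was set beside its percentile among 10000 random lists of the same size, with ties split evenly, as a description without a p-value. A list was called high at the 97.5th percentile or above.

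The genes named in the text follow a rule fixed in advance. In each comparison of 2 peak lists it takes from every gene list the 2 genes with the highest score among those with a peak in the treated or KO list and none in the other, and 1 gene in the opposite direction. It adds the 5 genes outside the lists with the highest score among peaks found in the treated or KO list alone. For shared sites it takes from every list the 2 genes with the highest p65 score. Nfkbia, Tnf, Il1b, Il6, Il12b, Il10, Cxcl10, Ccl5, Tnfaip3, Nos2, Socs1, Socs3 and Nos1 are given whatever their values, and fewer genes are named where the rule takes over 30. Some genes the rule takes are not reported here.

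The alternatives fixed in advance were an overlap of 50% of the shorter peak, centres within 500 bp, at least 8-fold enrichment over IgG, lists of equal length, leaving out regions called in all 12 lists, a gene end within 1 kb, the nearest gene end up to 100 kb, and random lists from genes with a peak in any library. Added after the data were seen were at least 8-fold over the local background, the gene span or 10 kb of it, and the same lowest score in both SOCS1 control lists. An alternative counts as a move where a share leaves its 95% interval or a count or ratio changes by over 1.5 times.

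Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap and gene list code was tested on simulated data with known answers.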

Results

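Sites of p65 (RELA, the NF-κB subunit that activates inflammatory genes) and of SOCS1 (a feedback inhibitor of cytokine signalling) were mapped by CUT&RUN in mouse bone-marrow-derived macrophages. The cells were wild type (WT) or a knockout (KO) that the study's design text names as NOS1, the neuronal nitric oxide synthase. They were left untreated (control) or given 100 ng/mL lipopolysaccharide (LPS, the bacterial product sensed by TLR4) for 30 min or 8 h. The labels do not state the KO gene elsewhere, and the study's title is about SOCS1; in cells without SOCS1, SOCS1 peaks would be antibody background. Each of the 12 peak lists comes from 1 library, so no difference between groups was tested, and every interval below covers counting error only.

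The p65 lists held 9643 peaks in WT control cells, 36030 after 30 min of LPS and 31007 after 8 h; the KO lists held 10721, 43124 and 25811. The SOCS1 lists held 9438, 19631 and 13720 peaks in WT and 24270, 19931 and 15633 in KO. Depth ranged from 7.69 to 18.4 M tags for p65 and from 6.93 to 9.74 M tags for SOCS1, and 2.12% to 15.2% of the tags lay in peaks. The IgG count was at its floor of 0.5 tags under 91.4% of the p65 peaks and 88.0% of the SOCS1 peaks of the KO control cells, against 14.7% to 43.0% in the other 10 lists. The 12 lists cover 96700 separate regions, of which 50202 (51.9%) are in a single list and 208 in all 12.

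**Figure D1:**
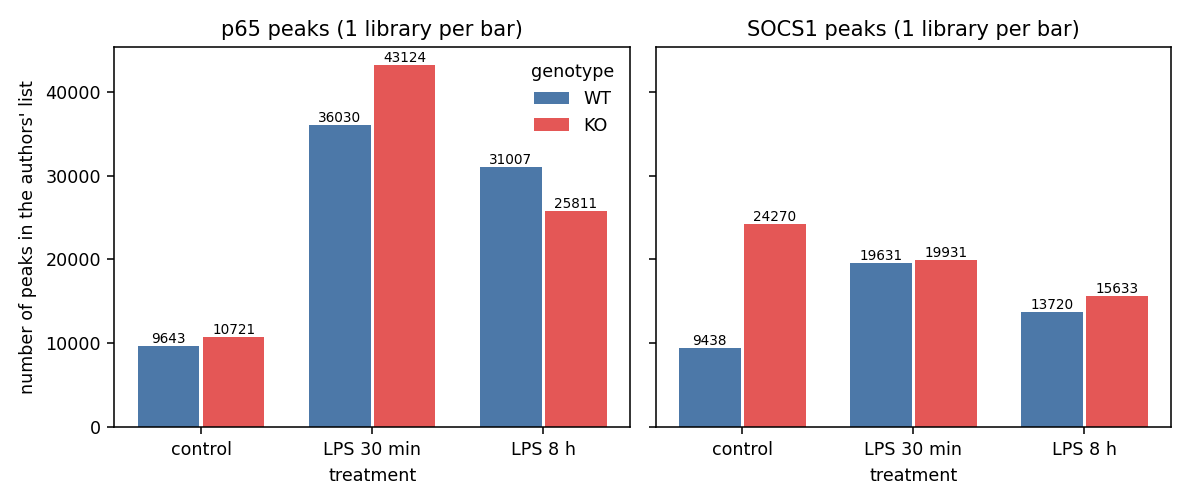
Number of peaks in each of the 12 lists, by antibody, genotype and treatment. Each bar is 1 library.

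In WT macrophages, LPS was followed by p65 peaks at genes of the NF-κB response itself, at cytokine genes and at interferon-stimulated genes. All 18 NF-κB subunits and feedback inhibitors had a p65 peak within 10 kb of a gene end at 30 min and at 8 h, against 14 in control cells; Traf1 (a TNF-receptor adaptor, score 127.5) and Relb (an NF-κB subunit, 110.5) led the genes without a control peak at 30 min. All 20 pro-inflammatory cytokines had a peak at both LPS times, against 13 in control cells, among them Il12b (a subunit of IL-12 and IL-23, 77.5) and Csf2 (GM-CSF, 66.5). Of the 26 interferon-stimulated genes, 10 had a p65 peak in control cells, 24 at 30 min and 26 at 8 h; Gbp5 (a guanylate-binding protein, 88.5) and Ifnb1 (interferon beta, 56.5) were new at 30 min and Ifit2 (55.5) at 8 h. The strongest new sites outside the gene lists at 30 min were at Tnfaip2 (induced by TNF, 173.0), Kdm6b (an H3K27 demethylase, 157.0), Pim1 (a kinase, 151.5), Zfp719 (149.0) and Gm4606 (147.5). At 8 h they were at Ctu1 and Siglece (a sialic acid receptor), which have an end within 10 kb of the same peak (171.5), and at Adora2a (an adenosine receptor, 154.0).

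Genes of many other functions also had p65 sites after LPS in WT cells. The counts in control cells, at 30 min and at 8 h were 14, 23 and 23 of 23 immediate-early genes, among them Zfp36 (which destabilises cytokine mRNA, 142.5) and Egr2 (121.0). Cell death genes counted 8, 16 and 15 of 16, among them Mcl1 (a survival factor, 148.5) and Casp1 (125.0). The counts were 25, 30 and 30 of 30 JAK-STAT and SOCS genes, 13, 17 and 16 of 18 chemokines and 17, 24 and 21 of 26 TLR4 signalling genes. They were 6, 15 and 14 of 15 anti-inflammatory and tolerance genes, 12, 20 and 21 of 22 antimicrobial and redox genes, and 10, 18 and 18 of 18 antigen presentation genes. Glycolysis genes counted 9, 19 and 19 of 21, macrophage identity genes 13, 20 and 18 of 20, cholesterol genes 8, 15 and 14 of 15, and alternative activation genes 6, 12 and 12 of 16. Housekeeping genes counted 10, 15 and 14 of 15, so p65 peaks were not limited to inflammatory genes. Genes of other cell types counted 2, 3 and 6 of 12 neutrophil markers, 4, 9 and 6 of 14 lymphocyte markers, 7, 8 and 8 of 10 dendritic cell markers, and 0, 7 and 3 of 20 neuronal and hepatic genes. Hk3 (a hexokinase, 12), Ifi44 (10.0) and Elane (neutrophil elastase, 9.0) had a control peak and none at 30 min.

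Among all 21887 protein-coding genes, 28.4% had a p65 peak in WT control cells, 58.9% at 30 min and 52.6% at 8 h. Of the genes without a control peak, 45.4% had a peak at 30 min, compared with 15 of 16 interferon-stimulated genes and 7 of 7 cytokines (percentiles 100.0 and 99.8 among 10000 random gene lists of the same size) and 7 of 20 neuronal and hepatic genes (percentile 17.5). Of the p65 sites at 30 min, 12.1% (95% interval 11.8 to 12.5) overlapped a control peak, where lists independent within all called regions would share 9.96% and random placement on the genome gave 0.244%. At 8 h 13.2% (12.8 to 13.6) did. Of the control peaks, 45.2% were called again at 30 min and 42.4% at 8 h. Of the 30 min sites, 46.3% (45.8 to 46.9) were called again at 8 h. The lists were 3.74 and 3.22 times as long as the control list, and the LPS libraries were also deeper (13.3 and 10.6 M tags) than the control library (7.69 M tags).

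**Figure D2:**
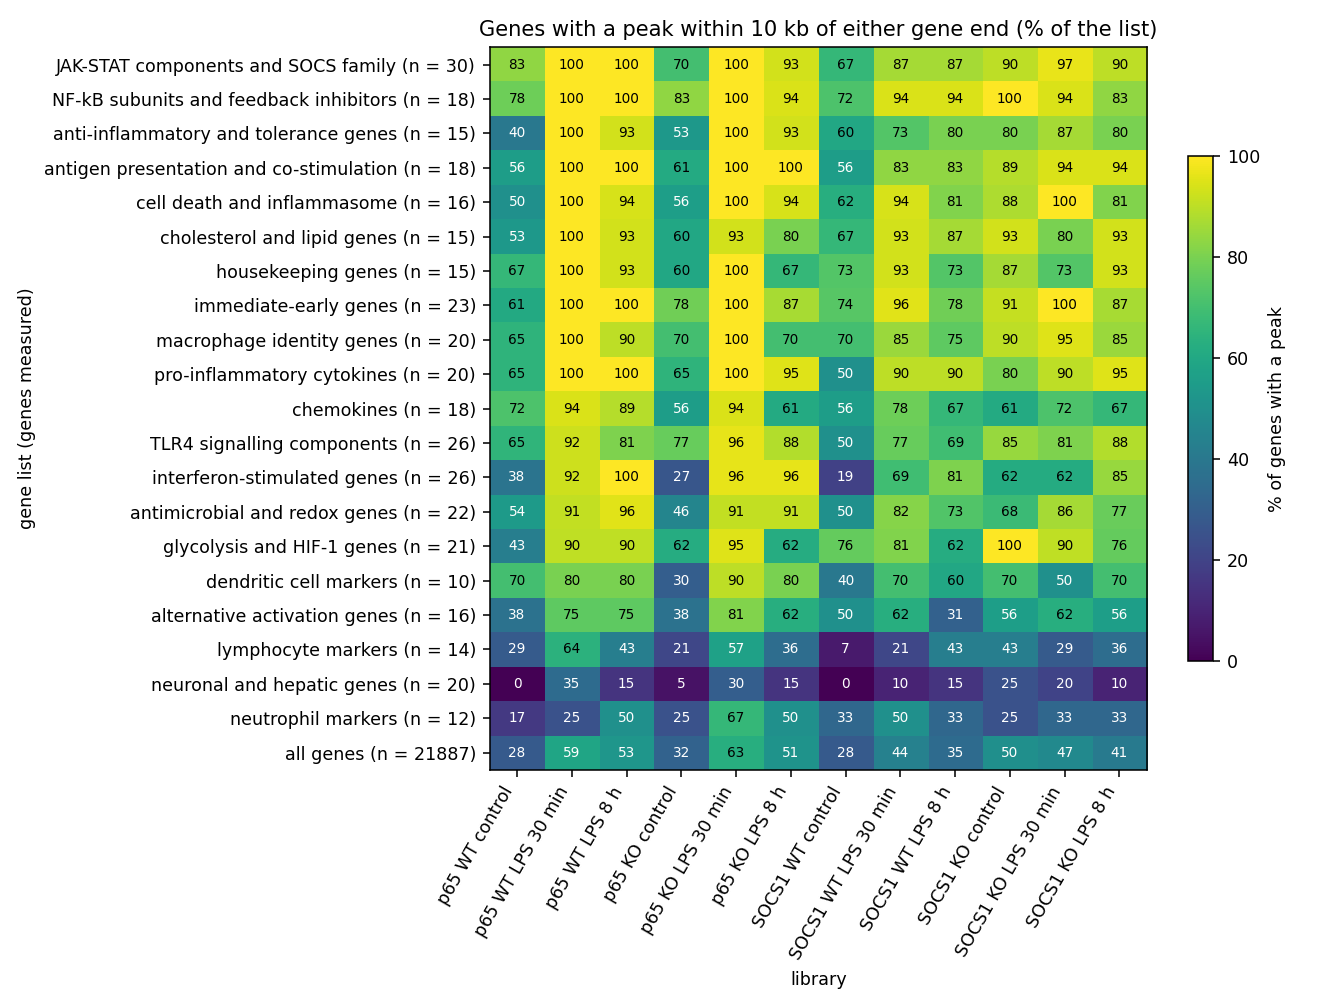
Share of each gene list with a peak within 10 kb of a gene end in each library. The number in each cell is the percent of the list.

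In KO macrophages, p65 was also called at NF-κB, cytokine and interferon-stimulated genes after LPS. The counts in control cells, at 30 min and at 8 h were 15, 18 and 17 of 18 NF-κB genes, 13, 20 and 19 of 20 cytokines and 7, 25 and 25 of 26 interferon-stimulated genes. New sites at 30 min included Il27 (a cytokine of the IL-12 family, 168.0), Fpr2 (a formyl peptide receptor, 149.5), Acod1 (which makes itaconate, 130), Gbp2 (107.0) and Tnfaip3 (the NF-κB inhibitor A20, 103.5). New sites at 8 h included Fpr2 (201.5), Gbp2 (188.0), Il1a (interleukin-1 alpha, 146.5), Acod1 (145.0) and Sod2 (a mitochondrial superoxide dismutase, 142.0). Outside the lists, Txlnb had the strongest new p65 site at both times (266.5 and 239.5), followed at 8 h by Slc31a2 (a copper transporter, 219.0). Chemokines counted 10, 17 and 11 of 18 in KO cells, and control peaks at Il6st (a cytokine receptor subunit, 20.5) and Ccl9 (18.0) were absent at 8 h. Of the KO sites, 12.4% (12.1 to 12.7) at 30 min and 15.1% (14.7 to 15.6) at 8 h overlapped a control peak. The KO list was 4.02 times as long as its control at 30 min and 2.41 times at 8 h; with only peaks at least 8-fold above their local background, the 8 h ratio is 1.53.

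SOCS1 was called at interferon-stimulated and cytokine genes after LPS in WT macrophages. Of the 26 interferon-stimulated genes, 5 had a SOCS1 peak in control cells, 18 at 30 min and 21 at 8 h; of the 20 cytokines, 10, 18 and 18 did. Of all genes, 28.2%, 43.9% and 34.9% did. At 30 min the genes without a control peak included Psmb9 (an immunoproteasome subunit, 60.5), Ctsb (cathepsin B, 54.5), Ifngr1 (the interferon gamma receptor, 50), Ccl5 (a chemokine, 45.5), Irf9 (an interferon response factor, 39.5) and Il12b (34.0). The NF-κB inhibitor genes Nfkbia (28.5) and Tnfaip3 (24.0) were also among them. At 8 h Ccl5 (54.5), Spi1 (the macrophage factor PU.1, 50.5), Gbp2 (49.5), Nr1h3 (the oxysterol receptor LXR alpha, 49.5) and Il27 (44.5) led. Outside the lists, Mllt6 had the strongest new SOCS1 site at both times (106.0 and 107.5), and Kdm6b (101.0) and the heat shock gene Hspa1b (99.5) followed at 30 min. Control peaks at Irf3 (an interferon-inducing factor, 32.0), Tbp (30) and H2-D1 (22.5) were absent at 30 min, and that at Klf6 (30) was absent at 8 h.

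In KO macrophages many of these genes had a SOCS1 peak without LPS, as did 49.8% of all genes. Interferon-stimulated genes counted 16 in KO control cells, 16 at 30 min and 22 at 8 h; NF-κB genes counted 18, 17 and 15 of 18, against 13, 17 and 17 in WT cells. New SOCS1 sites in KO cells were at Junb (an AP-1 subunit, 29.5 at 30 min and 92.5 at 8 h), Socs1 itself (31.0 and 56.0), Ccl5 (34.5 and 55.5) and, outside the lists, Tgif1 (104.0 and 81.5). Control peaks at Spi1 (45.0) and, at 8 h, Nfkbia (22.5) were absent. The WT list was 2.08 and 1.45 times as long as its control, whereas the KO list was 0.821 and 0.644 times as long. In WT cells 16.2% (15.7 to 16.7) of the 30 min sites and 21.8% (21.1 to 22.5) of the 8 h sites overlapped a control peak; in KO cells 32.5% (31.8 to 33.1) and 34.0% (33.2 to 34.7) did, where independent lists would share 25.1%. The KO control library kept 35.7% of its SOCS1 tags after reduction to 1 tag per bp, the lowest of the 12.

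Nos1, the gene named as knocked out, had peaks in KO lists alone. Its window on chromosome 5 (117856839 to 117968840) held 0 peaks in the 6 WT lists and 17 in the KO lists: 6 and 4 for p65 at 30 min and 8 h, and 1, 4 and 2 for SOCS1 in control cells, at 30 min and at 8 h. In the p65 KO 30 min list the highest score there was 110, at 117872377 to 117872599, where the IgG count was at its floor. The SOCS1 peaks with the highest score in this window lay within 1 kb of it, at 117872240 to 117872636 at 30 min (score 22) and 117871940 to 117872314 at 8 h (score 30). Nos1 had more KO peaks than any other gene without a WT peak, the next being Prrc1 with 10. Peaks inside the gene, such as those of p65 in KO cells at 30 min at 117872377 to 117872599 and 117911525 to 117911747, require that this DNA is present. They argue against loss of the whole gene in KO cells. They do not show whether another part of it is deleted.

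**Figure D3:**
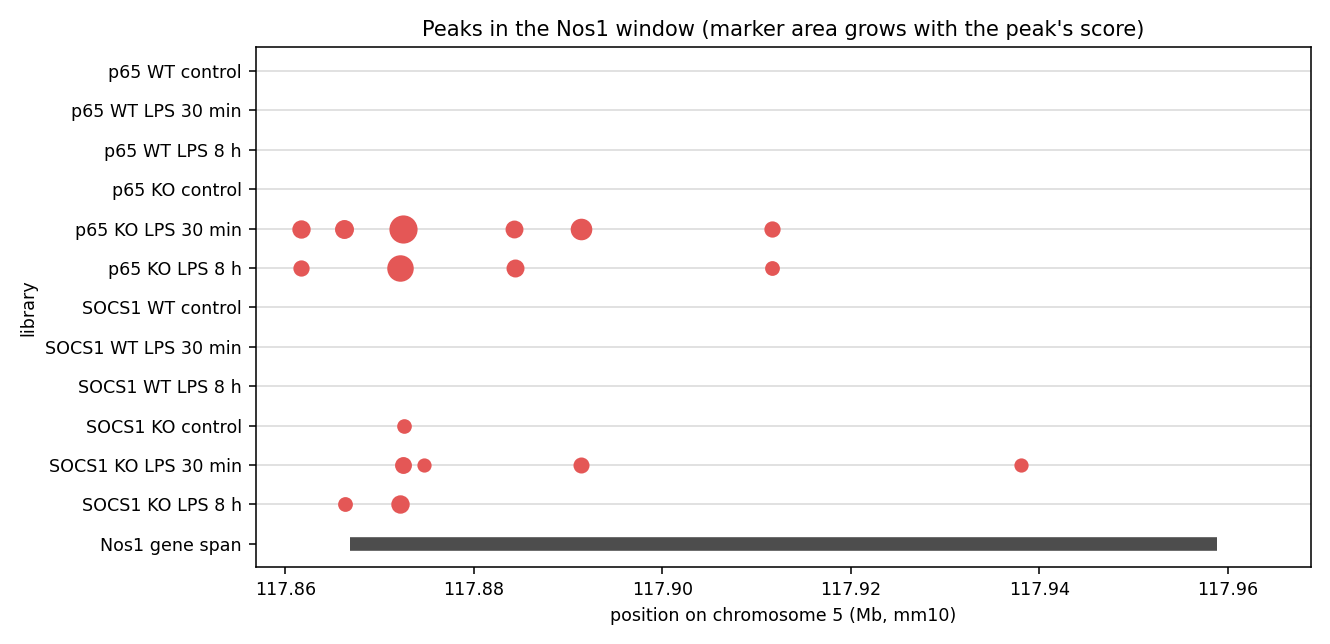
Peaks of the 12 lists around Nos1 on chromosome 5. Only KO lists have peaks in this window.

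With p65 at 30 min, most NF-κB, cytokine and interferon-stimulated genes had a peak in both genotypes. Of the 9 neutrophil markers without a WT peak, S100a8, Elane, Mpo, Ly6g and Prtn3 had a p65 peak in KO cells, that of Elane and Prtn3 being the same peak, compared with 16.3% of all such genes. In the KO list 8 of 12 neutrophil markers had a peak, beside 62.8% of all genes. The strongest KO sites at genes without a WT peak were at Cdk9 (the kinase of transcription elongation, 150.0), Ppp1r15b (117.5), Slc25a41 (113.0), Nos1 (110.0) and Hk3 (81.0). Cybb (the NADPH oxidase subunit, 16) and Apoe (12) had a peak in WT cells alone. Of the WT sites, 64.4% (63.9 to 64.9) were also called in KO cells, where independent lists would share 44.0%; in control cells the values were 19.4% (18.6 to 20.2) and 11.1%.

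At 8 h, chemokine, glycolysis and macrophage identity genes had p65 peaks in WT cells that the KO list lacked. These were Ccl5 (108.5), Ccl9, Cxcl1, Cxcl2 and Cxcl10 among 7 chemokines without a KO peak, and Slc2a1, Hk3, Pfkl, Pfkp, Pkm (pyruvate kinase, 45.0) and Vegfa among 8 glycolysis genes. Macrophage identity genes were Adgre1, Mitf, Tfec, Runx1, Ctsb (81.0) and Ctsd, 6 of 6. Of the 20 genes of this list, 18 had a WT peak and 14 a KO peak, and those without a WT peak had a KO peak. Il10 (an anti-inflammatory cytokine, 28.5), Tnip3 (70.0) and Zfp36 (39.5) also had WT peaks alone, as did the housekeeping genes Actb (61.0), Ppia, Sdha and Tfrc. Among all genes without a KO peak, 15.8% had a WT peak. In the opposite direction stood Nos1 (92.5), Ripk1 (a cell death kinase, 34.5) and the TLR4 signalling genes Irak1, Tollip and Ikbkg (18.5). Of the WT sites, 48.0% (47.5 to 48.6) were called in KO cells, against 26.7% for independent lists. Peaks of the KO 8 h list were 493 bp wide and those of the other 5 p65 lists 222 to 359 bp.

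SOCS1 peaks in control cells were found at Ctsb (62.5), Spi1 (45.0), Polr2a (43.5), Psmb9 (36.0) and Rela (the p65 gene, 33.0) in KO cells alone. Nfkbia, Nfkb1, Relb and Tnfaip3 joined Rela, so 5 of the 5 NF-κB genes without a WT peak had a KO peak, beside 35.4% of all such genes in this longer list. Junb (30), Actb (26.0), Ccl9 (23.5) and Socs1 (21.0) had one in WT cells alone. At 30 min H2-D1 (a class I MHC gene, 41.5), Ripk3 (31.5), Hk3 (30) and Tab1 (29.0) were KO-only, while Actb (52.0), Marcks (43.5), Irf9 (39.5) and Spi1 (31.0) were WT-only. At 8 h Klf6 (52.5), Sod2 (43.0), Lilrb4a (39.0) and Atf3 (a stress factor, 34.0) were KO-only, while Spi1 (50.5), Irf9 (38.0), Ccl9 (38.0) and Bcl2a1b (25.0) were WT-only. Of the WT sites, 36.5% (35.6 to 37.5), 37.0% (36.3 to 37.6) and 41.9% (41.0 to 42.7) were called in KO cells (25.1%, 20.6% and 16.1% for independent lists). The KO list was 2.57 times as long as the WT list in control cells, but 1.42 times when both lists keep the same lowest score. Scores are not scaled to depth, and fewer tags were kept at 1 per bp in the KO control library. The same score is thus a stricter cut there. At 30 min the ratio was 1.02 and became 0.94 with only peaks at least 8-fold above local background.

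SOCS1 and p65 shared sites at inflammatory genes, at more of them after LPS than before, as at genes in general. At 30 min in WT cells, 1 shared peak on chromosome 17 (35210049 to 35210303) lay within 10 kb of an end of Tnf and of Lta. It was 8169 bp from the end of Tnf, with a p65 score of 148.5 and a SOCS1 score of 57.0. Others were at Nfkbiz (an atypical IκB protein, 162.5 and 43.0), Tlr2 (a lipoprotein receptor, 137.5 and 59.0), Ccl2 (124.5 and 41.0), Irf1 (112.5 and 83.0) and Mcl1 (148.5 and 71.0). The feedback genes Zfp36 (142.5 and 52.5), Dusp1 (a MAP kinase phosphatase, 128.0 and 80.5) and Cish (a SOCS family member, 126.5 and 40.0) had shared sites as well. At 8 h the strongest shared sites in WT cells included Il1b (interleukin-1 beta, 175.0 and 51.5), Nfkbiz (133.0 and 37.0), Ccl3 with Ccl4 (127.5 and 56.0) and Gbp2 (103.5 and 49.5). In KO cells they included Tnf with Lta (193.5 and 52.0) at 30 min, and Il1b (244.0 and 55.5) and Tyk2 (a JAK kinase, 211.5 and 93.5) at 8 h.

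By gene group, 20 of 23 immediate-early genes, 15 of 20 cytokines, 14 of 18 chemokines and 22 of 30 JAK-STAT genes had a shared site at 30 min in WT cells, as did 14 of 15 housekeeping genes and 9 of 18 NF-κB genes (percentile 93.6). At 8 h, 19 of 26 interferon-stimulated genes, 17 of 20 cytokines and 12 of 18 NF-κB genes did. Of all genes, 10.1% had one in control cells, 31.9% at 30 min and 27.2% at 8 h. In WT control cells the counts were 5 of 20 cytokines, 5 of 18 chemokines, 5 of 18 NF-κB genes (percentile 98.2) and 4 of 15 housekeeping genes. In WT cells the NF-κB genes thus stood out less from random lists at 30 min than in control cells, but not at 8 h (percentile 99.98). KO cells did not show this, with 12, 14 and 13 of 18 NF-κB genes in control cells, at 30 min and at 8 h (percentiles 100.0, 99.98 and 99.98). Lymphocyte markers counted 1 of 14 at 30 min and 6 of 14 at 8 h (percentiles 2.1 and 89.4), and neuronal and hepatic genes 1 and 2 of 20.

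Of the WT SOCS1 sites, 25.5% (24.6 to 26.4) overlapped a p65 site in control cells, 53.1% (52.4 to 53.8) at 30 min and 66.2% (65.4 to 67.0) at 8 h, where independent lists would share 9.96%, 37.0% and 31.5%. The KO values were 16.3% (15.8 to 16.8), 60.1% (59.4 to 60.8) and 56.2% (55.4 to 56.9), against 11.1%, 44.0% and 26.7%. Of the p65 sites in WT cells, 24.9%, 28.9% and 29.3% overlapped a SOCS1 site, where independent lists would share 9.74%, 20.0% and 14.1%. In KO cells this share was lower after LPS than in control cells (36.9%, 27.9% and 34.0%, against 25.1%, 20.6% and 16.1% for independent lists). At 30 min in WT cells it was 4.74% in the lowest and 60.2% in the highest of 4 equal groups by p65 score. In WT cells, p65 sites of 30 min alone had a SOCS1 peak in 15.6% of cases at 30 min and 4.79% at 8 h, and p65 sites of 8 h alone in 9.04% and 17.1%. With lists of equal length, the KO share in control cells is above the WT share (29.6% and 25.3%), and the KO share at 8 h is above that at 30 min (48.2% and 46.4%).

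**Figure D4:**
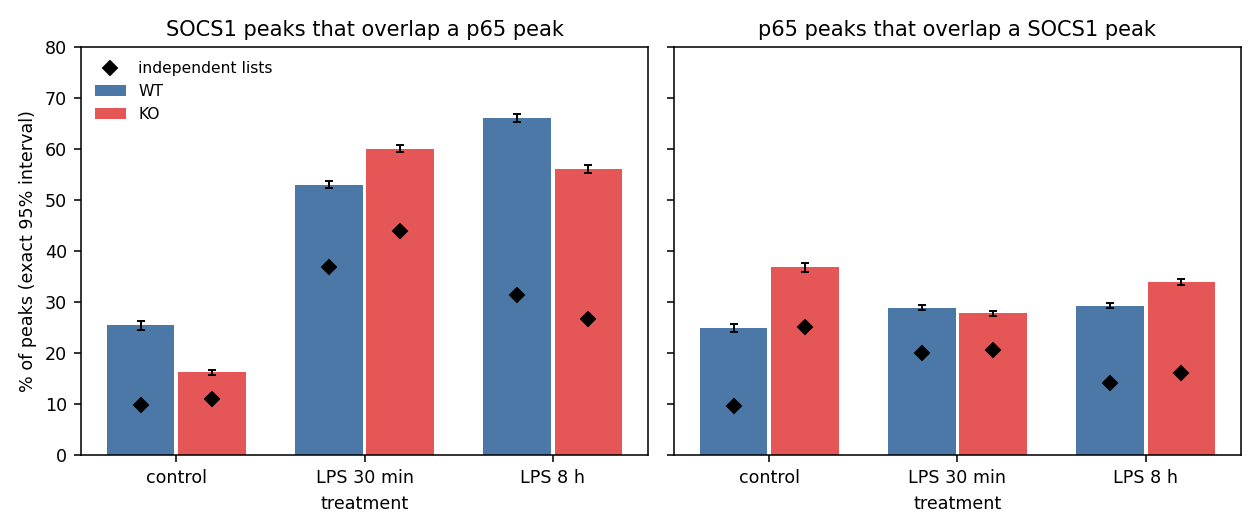
Share of SOCS1 peaks that overlap a p65 peak of the same genotype and treatment, and the reverse, with 95% intervals of counting error. Diamonds mark the share for independent lists.

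Of the 13 genes followed whatever their values, Tnf, Il1b and Socs3 (a JAK inhibitor) had a peak within 10 kb of a gene end in all 12 lists. Socs1 and Il12b had one in 10 lists, Nfkbia and Ccl5 in 9, Il6, Cxcl10 and Tnfaip3 in 8, Il10 in 7, and Nos2 (inducible nitric oxide synthase) and Nos1 in 5. With a gene end within 1 kb, the number of lists with a peak moved for 192 of the genes taken by the naming rule and did not for 143. Nfkbia, which encodes the inhibitor IκBα, had p65 peaks in all 6 p65 lists (118.0 at 30 min in WT cells), and Il6 had none in control cells of either genotype. Nos2 had p65 peaks in WT cells at 30 min and 8 h (26.5 and 36.5) and in KO cells at 30 min (32.5), and SOCS1 peaks at 8 h in both genotypes (19.5 and 22.5).

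Between 40.7% and 45.0% of the peaks of each list lay inside protein-coding genes and 29.0% to 35.3% outside them, in both cases more than 1 kb from any end of such a gene. Non-coding genes were not counted. Sites within 1 kb of a gene end made up 26.8%, 22.6% and 22.2% of the p65 peaks in WT cells (control, 30 min, 8 h) and 29.3%, 22.7% and 19.7% in KO cells. For SOCS1 they made up 28.3%, 27.5% and 26.5% in WT cells and 22.1%, 28.2% and 28.0% in KO cells. Of the SOCS1 sites shared with p65, 31.6% lay within 1 kb of a gene end at 30 min in WT cells, against 22.7% of the SOCS1 sites without p65. The difference was smaller at 8 h, with 27.5% against 24.4% in WT cells and 29.0% against 26.7% in KO cells.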

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

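All patterns below were picked after the results were seen. For the first pattern the tests of wide peaks and of depth, for the second those of the IgG library and of the lower-ranked peaks, and for the third those of DNA copies and of the flanking interval were also set after seeing the data; the others had their bounds written first.

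The p65 list of KO cells at 8 h lacks WT sites at Ccl5, Cxcl10, Ctsb, Pkm and Actb. Its peaks are 493 bp wide, and the peak caller filters on density over the 10 kb surroundings. Of the strongest of 4 equal groups of WT 8 h sites by score, 23.8% with low and 87.3% with high local fold are in the KO 8 h list, a gap 35.8 percentage points wider than in the KO 30 min list; yet the gap of the 375 bp wide SOCS1 KO 8 h list (31.2 points) is like that of the 260 bp wide WT list (29.5), so peak width as the reason stays open. Genes of the fixed lists that keep a KO peak had a local fold at the WT peak 4.12 higher in the median than the 42 genes that lack one (10.3 and 6.2), so sites near the local filter's threshold are likely among the absent ones; the differences for the p65 KO and WT 30 min lists were 0.97 and −0.925, but from 3 and 8 absent genes. Before the filters the KO 8 h library had more candidate peaks than the WT library (57745 and 52786). Its shorter list thus did not come from fewer candidates. The IgG filter removed 20.3% of the KO and 13.4% of the WT candidates, and the local filter 35.0% and 27.8%. Whether depth acted through these filters remains open. The KO 8 h library has 1.04 times the tags of the WT library but 0.93 times those kept at 1 per bp (9.02 and 9.7 M).

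The SOCS1 list of KO control cells, with sites at Rela, Nfkbia and Spi1, is 2.57 times as long as the WT list, and with it the LPS ratios turn: log2 1.06 in WT and −0.28 in KO at 30 min (difference −1.34), 0.54 and −0.63 at 8 h (difference −1.17, neither difference tested). The sparse IgG library is not the whole reason, as the KO library had 2.04 times as many candidate peaks before the IgG filter. The same lowest score of 9 leaves a ratio of 1.42, between the bounds set for a yes and a no. Scores are not scaled to depth, and at 1 tag per bp the KO library kept 35.7% of 8.06 M tags and the WT library 67.9% of 6.93 M. The same score is thus a stricter cut for KO, and the fall to 1.42 does not show that a lower threshold made the excess. At equal length the KO peaks were found in the 10 other lists more often than the WT peaks (WT minus KO −8.57 percentage points), but this bound was ill chosen, because the strongest 9438 peaks leave out the 14832 weaker ones that make the excess. Of the KO control peaks ranked below 9438 and down to 19631, 44.5% are found in another list, 17.2 percentage points below the lower share among peaks of the same ranks in the 30 min lists, but those have far longer p65 lists of their own time to be found in, so whether the weaker peaks are specific to this library stays open. A new KO control library of higher complexity would show whether the sites at NF-κB genes return.

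Nos1 has 17 peaks in KO lists and 0 in WT lists. Extra DNA copies in KO cells are not seen in the IgG tags, whose median at the 10 p65 peaks is 1.0 times that of the whole lists. The bound set was a rise of at least 3 times. With a median of 1.0 tag and peaks kept only at 4-fold or more over IgG, a smaller rise could be missed. Chance does not account for it, as 3 of 4019 genes (0.0746%) with 4 or more p65 peaks in KO cells at 30 min have no WT peak, Nos1 among them. A difference in strain background around the gene remains open, because KO-only p65 sites make up 7.62% (4.5 to 11.9) within 10 Mb and 9.51% in the genome. Altered DNA or new transcription at the targeted locus could give such peaks as well, and reads across Nos1 with RNA levels would tell them apart.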

How the results depend on the processing

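The settings with at least 8-fold over local background, the gene span and the same lowest score were added after the results were seen; all others were fixed first. Counting each main result under each setting, 133 values moved, 1 reversed and 155 did not; among further results 416 moved and 1678 did not. Shares move easily here because their 95% intervals of counting error are narrow, and the cause of a move was not tested. No paired analysis was possible because each group has 1 library, so no pair repeats a comparison; matching WT and KO lists across the 3 treatments would take treatments as replicates and was not done. The motif counts and their 2 alternatives (a wider window and stricter peaks) were not run for want of a genome sequence. Under every setting the share of SOCS1 sites with p65 was higher at both LPS times than in control cells, in both genotypes. In WT cells it was also higher at 8 h than at 30 min under every setting. The equal-length setting matched the 2 lists of each pair, not lists across times. The share for independent lists also rose, from 9.96% in WT control cells to 37.0% and 31.5%. In KO cells it rose from 11.1% to 44.0% and 26.7%. The rise after LPS is thus not separated from list length. Below, "new" shares are LPS sites not called in control cells, in the order p65 WT, p65 KO, SOCS1 WT, SOCS1 KO, each at 30 min and 8 h. Shares of WT sites found in KO and of SOCS1 sites with p65 are given for control, 30 min and 8 h.

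With the main setting the new shares were 87.9% and 86.8%, 87.6% and 84.9%, 83.8% and 78.2%, and 67.5% and 66.0%. WT sites found in KO were 19.4%, 64.4% and 48.0% for p65 and 36.5%, 37.0% and 41.9% for SOCS1. SOCS1 sites with p65 were 25.5%, 53.1% and 66.2% in WT and 16.3%, 60.1% and 56.2% in KO.

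At least 8-fold over local background left 5060, 19365 and 16416 p65 peaks in WT (control, 30 min, 8 h) and 6421, 24263 and 9841 in KO; SOCS1 kept 6247, 13049 and 7411 in WT and 12270 and 7802 in KO after LPS. The new shares that moved were 90.2% and 89.5% for p65 WT, 88.9% for p65 KO at 30 min, 85.5% for SOCS1 WT at 30 min, and 71.8% and 67.6% for SOCS1 KO. WT sites found in KO were 15.1%, 65.8% and 35.2% for p65 and 29.8%, 32.3% and 35.6% for SOCS1. SOCS1 sites with p65 were 17.6%, 46.7% and 62.6% in WT and 11.3%, 52.3% and 42.3% in KO. The p65 KO ratio of 8 h to control moved from 2.41 to 1.53, the SOCS1 ratio of KO to WT at 30 min went from 1.02 to 0.94, and 11 of 17 KO peaks stayed at Nos1. With the same lowest score, which is not scaled to depth, the SOCS1 control ratio of KO to WT moved from 2.57 to 1.42.

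At least 8-fold over IgG left 6139 SOCS1 peaks in WT control cells. The new shares were 92.8% and 92.1%, 88.3% and 86.7%, 91.9% and 88.2%, and 71.1% and 71.5%. WT sites found in KO were 15.3%, 54.5% and 37.1% for p65 and 29.5%, 25.2% and 28.2% for SOCS1. SOCS1 sites with p65 were 19.9%, 46.0% and 63.3% in WT and 15.7%, 55.9% and 49.7% in KO.

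Where overlap must reach 50% of the shorter peak, the new shares were 89.5% and 88.3%, 89.5% and 88.1%, 85.8% and 81.2%, and 75.3% and 73.4%. WT sites found in KO were 14.8%, 61.0% and 41.2% for p65 and 28.4%, 31.7% and 36.0% for SOCS1. SOCS1 sites with p65 were 20.7%, 48.7% and 61.0% in WT and 12.4%, 50.6% and 49.3% in KO. With centres within 500 bp, the new shares were 85.4% and 84.0%, 84.7% and 84.0%, 80% and 74.2%, and 65% and 62.7%. WT sites found in KO were then 22.5%, 76.1% and 52.2% for p65 and 40.6%, 43.2% and 47.8% for SOCS1, and SOCS1 sites with p65 28.4%, 63.6% and 77.5% in WT and 18.0%, 68.3% and 57.9% in KO.

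At equal list lengths the new shares were 77.9% and 81.3%, 73.8% and 75.8%, 74.0% and 73.8%, and 68.8% and 69.2%. For p65, WT sites found in KO were 18.4%, 61.0% and 51.5%; for SOCS1 those that moved were 28.3% in control cells and 40.6% at 8 h. SOCS1 sites with p65 were 45.1% and 49.3% in WT after LPS and 29.6%, 46.4% and 48.2% in KO. Leaving out regions called in all 12 lists gave new shares of 88.3% and 87.3% for p65 WT, 88.0% and 85.5% for p65 KO, and 84.5% and 79.2% for SOCS1 WT. In control cells it gave 18.0% (p65) and 35.4% (SOCS1) of WT sites found in KO, and 24.2% (WT) and 15.7% (KO) of SOCS1 sites with p65.

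Of the 20 gene lists, the number at or above the 97.5th percentile was 12, 15 and 15 for p65 WT, 12, 15 and 11 for p65 KO, 14, 15 and 15 for SOCS1 WT and 12, 14 and 15 for SOCS1 KO. With a gene end within 1 kb, it moved to 6 for p65 in WT control cells, 6 and 5 in KO cells at control and 8 h, 7 and 9 for SOCS1 WT at control and 30 min, and 9 for SOCS1 KO at 30 min. With random lists from genes that have a peak in any library, it moved to 8 for p65 WT at 8 h, 5 and 3 for p65 KO at control and 30 min, 7 for SOCS1 in control cells of either genotype, and 9 for SOCS1 KO at 30 min. The gene span or 10 kb of it and the nearest gene end up to 100 kb moved none of the 12 by the rule for counts. Changes too small to count as a move were still seen. For p65 KO at 8 h the number rose from 11 to 14 with the gene span and to 16 with the nearest gene end. For p65 WT at 8 h it rose from 15 to 16 with both, while for p65 KO at control it fell from 12 to 10 with both. The lower number for p65 in KO than in WT cells at 8 h thus depends on how peaks are linked to genes.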

Other observations

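The gene groups here were picked after their values were seen, and no difference was tested. Of 8 TLR4 signalling genes without a SOCS1 peak in WT cells at 8 h, Irak1, Irak4, Traf6 (the ubiquitin ligase downstream of the IRAK kinases), Tollip, Chuk and Ikbkg, 6 in all, had a peak in KO cells, compared with 18.8% of all such genes; in the opposite direction Tab2 had a peak in WT cells, 1 of 3. Of 5 immediate-early genes without a SOCS1 peak in WT cells at 8 h, Egr3, Atf3, Klf6 (52.5) and Maff, 4 in all, had one in KO cells, beside the same 18.8%. In control cells p65 had a peak in KO alone at Irf3 (29.0), Fosb (an AP-1 subunit, 25.0) and Pgk1 (a glycolytic enzyme, 25.0), and in WT alone at Gsdmd (the pore-forming protein of pyroptosis, 43.0) and Socs1 (23.5). Of 9 JAK-STAT genes without a KO control peak, Socs1, Socs4, Socs7, Jak1, Stat2 and Ifnar1 (the type I interferon receptor) had a p65 peak in WT control cells, beside 16% of all such genes; in the opposite direction Tyk2 and Ptpn1 did, 2 of 5 beside 19.7%.

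Of the 6 macrophage identity genes without a SOCS1 control peak in WT cells, 5 had a peak at 8 h, Spi1 (50.5) among them. Of the alternative activation genes, which mark macrophages exposed to IL-4, 4 of 16 had a shared p65 and SOCS1 site at 8 h in WT cells, near the level of all genes (27.2%, percentile 43.6 among random lists).

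Of the tests below, that with SOCS1 of the other genotype was set after seeing the results; the others had their bounds written first, while the patterns were picked from the results. If SOCS1 peaks only repeated open sites or p65 signal of any time, SOCS1 at 30 min and at 8 h should favour p65 sites of 30 min alone and of 8 h alone in the same ratio. The odds of SOCS1 at p65 sites of 8 h alone, over those of 30 min alone, were instead 3.64 times higher at 8 h than at 30 min in KO cells and 7.61 times in WT cells. Lists of the same genotype and time share an IgG library, but with SOCS1 of the other genotype, called against other IgG libraries, the ratios were still 2.73 at WT and 2.12 at KO p65 sites. A shared IgG library is thus not the whole reason, though it could be a part. At KO p65 sites, however, WT SOCS1 at 8 h lay at 13.1% of the sites of 30 min alone and 9.53% of those of 8 h alone, so across genotypes it did not favour the 8 h sites there. The KO 8 h p65 list held only 23.8% of the strong WT 8 h sites of low local fold. KO sites of 30 min alone may therefore include sites missed at 8 h, a limit that also holds for the KO ratio of 3.64. SOCS1 may follow p65 within each time point, but signal shared by libraries of the same genotype and time could do the same; a SOCS1 library from cells without SOCS1 would separate them.

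The share of SOCS1 sites within 1 kb of a gene end was higher without p65 in 0 of 6 libraries, so these sites were not the nearer ones. Gene ends include the outermost start of each protein-coding gene, and 18.5% to 26.7% of the sites without p65 lay near an end, so most are not at such a start. Starts inside genes are not in the gene table, and starts of non-coding genes were not counted. In WT control cells 36.5% of the SOCS1 sites with p65 and 25.5% of those without lay within 1 kb of a gene end.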
